A study of Glycine max and Glycine soja with 4 samples.

How the data were processed

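RNA from leaves of soybean was measured by high-throughput sequencing in 4 libraries, 1 for each combination of 2 genotypes and 2 treatments. Per the labels' protocols, plants with 3 fully expanded trifoliates were used, and the second fully expanded leaf was either left untreated or fed upon for 24 h by 3 larvae of the cotton bollworm Helicoverpa armigera in instar 3. Per the labels' protocols, mRNA was purified on oligo(dT) beads, cDNA was primed with oligo(dT), and paired-end reads of 35 bp were made on an Illumina HiSeq2000. The aligner, the counter, the genome build and the treatment of reads that match several genes are not given in the sources used here. Reads this short cannot always separate near-identical copies, so values of members of large families (heat shock proteins, lipoxygenases, histones) are uncertain between copies. No strand setting is given either.

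The authors deposited 1 gene table per pair of libraries, and each library stands in 2 of them. The whole-number counts per gene model, deposited under a heading for raw intensity, were taken as counts. They were checked by comparing the 87854 values that 2 tables hold for the same library and gene, of which 0 differed. The deposited tables also hold per-million values (headed TPM), which per the file headers belong to the same libraries. The count divided by this value is the same for every gene of a library, so gene length does not enter and the values are reads-per-million values (RPM). The authors set values of 0 to 0.01. The library totals implied by these values are 5660871, 5679012, 6031113 and 5656109 reads in the order Tianlong 2 control, Tianlong 2 attacked, ED059 control and ED059 attacked, and the gene counts sum to 41.4%, 41.0%, 40.7% and 41.1% of them. The deposited log2 ratio is the authors' log2 of the RPM values of the libraries of a table. The deposited p-value and the deposited FDR score compare 1 library with 1 other, and the test behind them is not given in the sources used here. The FDR column exceeds 1 for 876 genes of the Tianlong 2 feeding table and 645 genes of the table of attacked leaves, so it was treated as a score. The authors' deposited tables of pathways and biological processes give numbers of called genes with an enrichment p-value. Every gene of the pathway tables that was found in the gene tables has an FDR of 0.001 or less and an absolute log2 ratio of 1 or more. Their background was 42032 annotated genes, whether or not measured in leaves, so these p-values were not rescaled and serve only as the authors' own values. Tables of cellular components and molecular functions were not used here.

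The union of the tables holds 25632 gene models at 25316 loci. Gene descriptions are the best protein database hits in the deposited tables: 24890 models have a description, of which 14910 are not merely uncharacterized or hypothetical. The reference gene table supplied (Glycine_max_v4.0) contains 0 of the gene identifiers, so no coordinates are given. Total gene counts were 2344329 in Tianlong 2 control, 2330109 in Tianlong 2 attacked, 2454031 in ED059 control and 2326840 in ED059 attacked leaves. At these depths 1 count equals 0.427, 0.429, 0.407 and 0.43 CPM of a library's unscaled gene counts, in the same order. A count of 0 allows up to 3 counts, which is 1.28, 1.29, 1.22 and 1.29 CPM.

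Counts were scaled by the trimmed mean of M-values (TMM) in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) over the 17622 gene models with 10 or more counts in at least 1 library. Levels are counts-per-million values of the scaled library (CPM). Log2 folds were computed with a prior count of 2. With 1 library per group no pairwise difference has a replicate, so genes were described by size, 2-fold or more, and not tested. Intervals of 95% for a single gene are exact, Poisson for a level and conditional binomial for a ratio. They cover counting error only. A fold against a library at 0 is a lower bound from a floor of 3 counts in that library. It leaves out counting error in the other library, so it is not the limit of the 95% interval, which reaches lower. For Glyma07g32030.1 after feeding in Tianlong 2 the bound was 248-fold and the limit of the interval 201-fold.

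Gene lists were fixed before the data were examined, by words in the deposited descriptions. They cover jasmonate synthesis, JAZ repressors, protease inhibitors, vegetative storage proteins, flavonoid enzymes, phenylpropanoid entry enzymes, terpenoid synthases, pathogenesis-related proteins, phenol oxidases and peroxidases, WRKY factors, ethylene synthesis and response factors, MYB factors, disease resistance proteins, receptor kinases, calcium-binding proteins, photosystem and antenna proteins, Calvin cycle enzymes, heat shock proteins, glutathione S-transferases, cytochromes P450, cell wall proteins, starch and sucrose enzymes and clock genes. Lists of seed, nodule, pollen, dividing-cell, senescence and ribosomal proteins served as markers of other organs or states. Of these 29 lists, 28 had members; the vegetative storage protein list had 0. Lists by pathway number were also planned, but the pathway tables list only genes the authors had called, so they were not used. The median log2 fold of each list was placed among 10000 random lists of the same size, matched on mean expression in 10 classes. This describes these libraries and is not a test of the conditions. Splits of lists by family, such as histones or expansins, were made after the list values were seen. The words catch some members that do other things: 7 disease resistance members are multidrug or other resistance proteins, 17 of the 32 jasmonate members are lipoxygenases, of which 5 are named as 9S enzymes outside jasmonate synthesis, and 17 genes stand in 2 or more lists.

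The only test was an additive model of genotype and treatment over the 4 libraries, fitted with edgeR's quasi-likelihood method and Benjamini-Hochberg adjustment. Its 1 residual degree of freedom is the difference of the responses of the genotypes, so it asks which effects are large against that difference. DESeq2 1.42.0 was the alternative tool. The fit was tested on simulated data with the real means and library sizes. With the estimated dispersion of 0.189 it recovered 17% of 100 simulated 4-fold changes and 83% of 100 simulated 16-fold changes of the treatment effect among 16354 genes, with 6 false calls. For the genotype effect it recovered 12% and 73%, with 3 false calls. Every simulated gene had this same dispersion and no effect of the other factor, unlike real genes, so recovery in the real data may be lower.

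Named genes were chosen by rules set at the same time as the lists, except lipoxygenase L-5, which was named after its values were seen. For each pairwise comparison these are the 6 highest and 6 lowest log2 folds among described genes with 100 or more counts in the higher library, and in each list the 2 largest folds of 2 or more among members with 50 or more counts. For the additive fit they are the 5 highest and 5 lowest folds past an adjusted p of 0.05, and for the difference of responses the 5 highest and 5 lowest among described genes with 100 or more counts. The rule for the additive fit was written for the treatment effect and applied to the genotype effect too. Uncharacterized proteins were passed over. Alternatives were other scalings (gene count totals, DESeq2 size factors, the authors' totals), other count minimums, another prior count, a 4-fold limit, and other models. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for intervals, lists and plots.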

Results

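Leaf transcripts of the soybean cultivar Tianlong 2 and the wild soybean line ED059 were compared with and without feeding by larvae of Helicoverpa armigera, a moth whose larvae chew leaves. The study asked how the response to the herbivore differs between the cultivar and the wild line. Each of the 4 groups is 1 library, so no value below has a replicate. Total gene counts were close, from 2326840 in attacked ED059 to 2454031 in control ED059, and between 20429 and 21668 gene models had a count. The 10 most abundant genes took between 9.5% of the counts, in control ED059, and 13.2%, in attacked ED059 leaves. Levels are TMM-scaled counts-per-million values (CPM), and intervals cover counting error only.

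Genotype separated the libraries more than feeding did. Across 17622 genes, which are not independent replicates, the log2 levels of the 2 Tianlong 2 libraries correlated at Pearson r = 0.844 and those of the 2 ED059 libraries at 0.865. Across genotypes r was 0.789 between control leaves and 0.718 between attacked leaves. Of the squared log2 differences among the libraries, 55.9% lay along genotype, 25.4% along treatment and 18.8% along the difference of the responses. Counting error alone would give 8.6% of the total.

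In Tianlong 2, leaves fed upon for 24 h had higher transcripts of phenylpropanoid and flavonoid enzymes and lower transcripts of heat shock proteins, jasmonate genes, protease inhibitors and cell wall enzymes than control leaves. Of 17622 genes, 2544 were higher and 2602 lower by 2-fold or more. The entry enzymes of the phenylpropanoid pathway, which turn phenylalanine into precursors of lignin and flavonoids, were higher by 2-fold or more for 11 of 12 members, with a median log2 fold of 1.47 (random lists -0.58 to 0.37). A phenylalanine ammonia-lyase, Glyma20g32135.1, stood at 31.6 CPM in control and 131 CPM in attacked leaves, a log2 fold of 2.02 (1.67 to 2.45). A 4-coumarate-CoA ligase, Glyma15g00390.1, was 5.65-fold higher. Of 62 flavonoid and isoflavonoid enzymes, 19 were higher and 10 lower, with a median of 0.55 (random -0.19 to 0.25). The 2 members named for the largest folds went the other way: the leucoanthocyanidin dioxygenase gene Glyma18g43136.1, of the anthocyanin branch, stood at 187 CPM in control and 16.7 CPM in attacked leaves, and Glyma07g18280.1, described alike, had 96 and 3 counts (log2 ratio interval -7.48 to -3.58). Cytochromes P450 had 36 members higher and 15 lower (median 0.41, random -0.10 to 0.26).

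The genes that stood highest above control in attacked Tianlong 2 leaves were of several kinds. A vacuolar-processing enzyme, Glyma17g34900.1, a protease that matures vacuolar proteins, stood at 86.3 CPM in control and 2560 CPM in attacked leaves, a log2 fold of 4.88 (4.68 to 5.11). A fasciclin-like arabinogalactan protein, Glyma15g09250.2, was at 0 counts in control leaves and at least 48.8-fold higher in attacked leaves. An auxin-induced protein, Glyma13g03510.1, was at least 44.6-fold higher from 0 counts. A boron transporter, Glyma15g01390.1, had 2 and 156 counts (log2 ratio interval 4.23 to 9.17), an inorganic pyrophosphatase, Glyma08g20820.1, 2 and 104 counts (3.64 to 8.59). Among pathogenesis-related proteins a glucan endo-1,3-beta-glucosidase, Glyma03g28870.1, had 3 and 138 counts (3.77 to 7.65), and a basic form of PR-1, Glyma15g06816.1, stood at 31.6 and 312 CPM. This list as a whole had 15 members higher and 20 lower of 72, with a median of 0.00. A peroxidase, Glyma10g05800.1, was at least 29.3-fold higher in attacked leaves.

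Heat shock genes were lower in attacked than in control Tianlong 2 leaves for 36 of 61 members and higher for 5, with a median log2 fold of -1.89 (random -0.23 to 0.24). The chaperones of this list keep other proteins from aggregating. Class I small heat shock proteins were among the 6 lowest genes of the comparison: Glyma07g32030.1 stood at 311 CPM in control leaves and at 0 counts in attacked leaves, at least 248-fold lower, and Glyma07g32110.1 was at least 94.4-fold lower. The class III protein Glyma07g04860.1 was at least 63.2-fold lower, the chaperone ClpB1, Glyma06g21910.1, at least 89.9-fold lower, and the low molecular weight protein Glyma19g01440.1 147-fold lower, with 1563 and 12 counts. The summed level of the list was 8040 CPM in Tianlong 2 control leaves, against 2350 CPM in attacked Tianlong 2, 2660 CPM in control ED059 and 2100 CPM in attacked ED059 leaves, so the Tianlong 2 control library stood apart from the other 3.

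Jasmonate genes were also lower in attacked Tianlong 2 leaves. Of 32 genes in the jasmonate synthesis list, 14 were lower and 3 higher (median -0.65, random -0.41 to 0.28). Lipoxygenase Glyma13g42340.1 stood at 245 and 10.5 CPM and the chloroplast lipoxygenase Glyma13g31280.1 at 157 and 12.1 CPM. The summed level of the list was 13300 CPM in control and 6550 CPM in attacked leaves. Against ED059 the list stood apart in control leaves (median -0.69, random -0.42 to 0.32) and not in attacked leaves (median 0.47, random -0.45 to 0.54). In attacked leaves 12 members were higher and 9 lower in ED059. The 2 members named for the largest folds there were lower in ED059. The chloroplast 13S-lipoxygenase Glyma11g13880.2 stood at 499 CPM in Tianlong 2 and 39.1 CPM in ED059. The 12-oxophytodienoate reductase Glyma14g39790.1 stood at 33.5 and 3.18 CPM. The summed level was 13500 CPM in control ED059 and 8580 CPM in attacked ED059 leaves, sums carried by lipoxygenase L-5, as given with ED059. By summed level attacked Tianlong 2 was the lowest of the 4 libraries. Of 5 JAZ genes, repressors that are themselves switched on by jasmonate, 3 were lower and 0 higher (median -2.62, random -0.98 to 0.70; -2.50 with members at 0 counts set to their bound). TIFY 10A, Glyma13g17180.1, stood at 163 and 8.78 CPM, a log2 fold of -4.09 (-4.92 to -3.58). Protease inhibitors, proteins that block digestion in the insect gut, were lower for 7 and higher for 3 of 14 members (median -1.19, random -0.67 to 0.30). The cysteine proteinase inhibitor Glyma14g04260.1 stood at 3110 and 241 CPM, and the Kunitz trypsin inhibitor Glyma09g28310.1 at 299 and 24.7 CPM. For JAZ genes and protease inhibitors the list median stood apart from ED059 in attacked leaves and not in control leaves, as given with the attacked leaves. Of the protease inhibitors, 4 were higher and 5 lower by 2-fold or more in control ED059 leaves, so single members differed there too. Single transcription factor genes went both ways: the WRKY 40 genes Glyma13g44730.1 and Glyma07g02630.1 were 14.7-fold and 10.3-fold lower and ERF109, Glyma07g33511.1, at least 41.4-fold lower, while the ethylene-responsive factor Glyma15g16260.1 was 6.84-fold higher. The WRKY list had 19 members higher and 11 lower (median 0.18, random -0.20 to 0.32).

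Cell wall and ribosomal protein lists were lower as well in attacked Tianlong 2 leaves, while cell division genes had 10 members higher and 20 lower of 129 (median 0.00). Of 115 cell wall genes, 52 were lower and 21 higher (median -0.61, random -0.14 to 0.18; -0.35 with members at 0 counts set to their bound). A xyloglucan endotransglucosylase, Glyma16g04950.1, which cuts and rejoins wall polymers, stood at 192 and 10.5 CPM, and a pectinesterase, Glyma17g04940.1, at 104 and 5.44 CPM. Ribosomal protein genes had 30 members lower and 2 higher of 162 (median -0.57, random -0.26 to 0.01). The antenna protein gene Glyma16g27995.1 stood at 9770 CPM in control and 1070 CPM in attacked leaves, while the photosystem list had a median of -0.32 (random -0.47 to 0.10). Scaling by gene count totals put the median log2 fold of all genes at 0.15 (0.00 with TMM) and gave 3266 higher and 2126 lower genes (60.6% higher, against 49.4% with TMM). The cell wall, ribosomal and photosystem medians kept their sign with scaling by gene count totals and with DESeq2 size factors, the scalings under which lists were rerun.

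**Figure D1:**
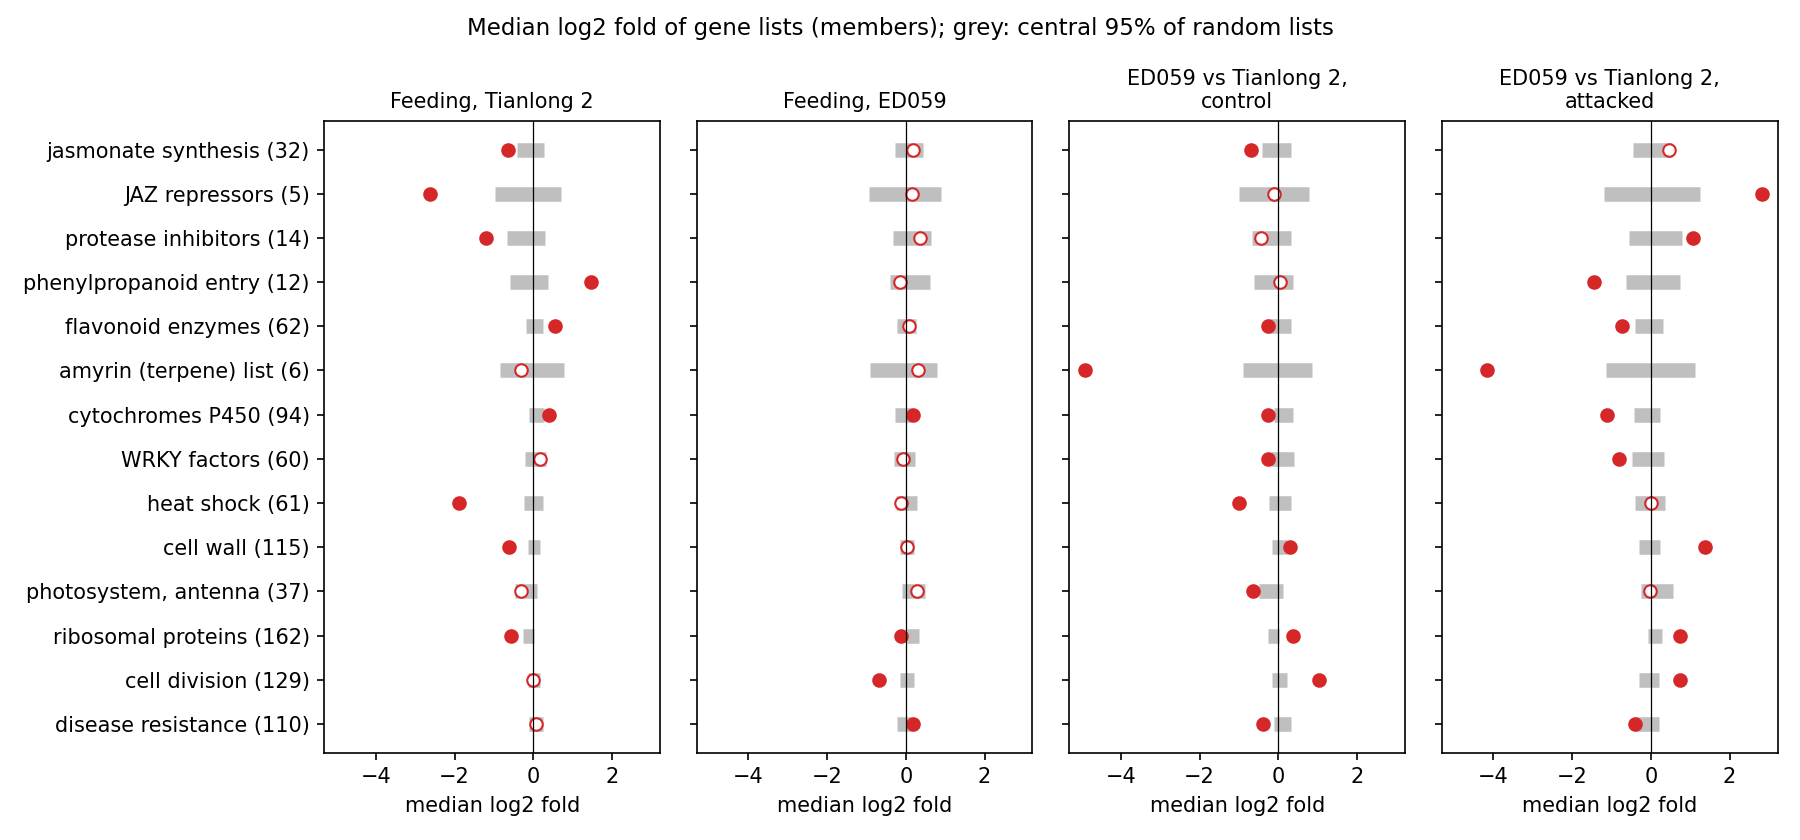
Median log2 fold of 14 gene lists (rows, with the number of members) in each of the 4 comparisons, on a linear axis of log2 units; filled points lie outside the central 95% of 10000 random lists matched on expression (grey bars), open points within it, and each comparison is 1 library against 1 other. JAZ repressors had medians of -2.62 after feeding in Tianlong 2 and 0.16 in ED059 (-0.07 with scaling by gene count totals), and phenylpropanoid entry enzymes 1.47 and -0.15.

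In ED059, attacked leaves had lower transcripts of cell division genes than control leaves, and single defence genes stood out as higher. Of 17622 genes, 2046 were higher and 3058 lower by 2-fold or more. A linoleate 9S-lipoxygenase, Glyma07g03920.2, an enzyme that oxygenates free fatty acids, stood at 45.1 CPM in control and 743 CPM in attacked leaves, a log2 fold of 4.02 (3.78 to 4.32). A Bowman-Birk proteinase inhibitor, Glyma18g46580.1, of a family that inhibits trypsin and chymotrypsin, stood at 37.4 and 545 CPM, a log2 fold of 3.83 (3.57 to 4.17). The auxin-responsive protein IAA26, Glyma07g01800.1, was 16.0-fold higher, a galactose oxidase-like gene, Glyma04g02880.1, 11.8-fold, the cytochrome P450 83B1 gene Glyma03g03560.1 10.6-fold and a proline-rich protein, Glyma15g23830.1, 9.65-fold. A dihydroflavonol reductase, Glyma18g10260.1, was at 0 counts in control leaves and at least 34.7-fold higher in attacked leaves.

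Of 129 cell division genes (histones, cyclins and kinesins), 47 were lower and 7 higher in attacked ED059 leaves (median -0.68, random -0.15 to 0.20). Histones were lower for 13 of 25 members with 0 higher (median -1.03), kinesins for 15 of 39 (median -0.61) and cyclins for 19 of 65 (median -0.34). The summed level of the list was 8350 CPM in control ED059, 5380 CPM in attacked ED059, 2730 CPM in control Tianlong 2 and 3310 CPM in attacked Tianlong 2 leaves, so the ED059 control library stood highest, and it enters both this comparison and that of control leaves. Cyclin A2, Glyma14g16130.2, stood at 46.6 and 6.82 CPM and histone H3, Glyma08g24380.1, at 84.0 and 25.0 CPM. The lowest genes of the comparison included receptor-like kinase Glyma13g27130.1 at 112 and 2.73 CPM, cellulose synthase-like protein G1, Glyma04g43470.1, at 181 and 6.82 CPM, glutaredoxin C9, Glyma13g30770.1, with 111 and 2 counts (log2 ratio interval -8.55 to -3.60), and the RING1 ubiquitin ligase Glyma02g12050.1 with 145 and 3 counts (-7.58 to -3.71). A 3-oxoacyl-acyl-carrier-protein reductase, Glyma18g01280.1, had 168 and 3 counts (-7.79 to -3.93), and STRUBBELIG-receptor family 6, Glyma07g05230.1, 131 and 3 counts (-7.44 to -3.56).

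Jasmonate, JAZ, protease inhibitor and phenylpropanoid lists lay within their random lists in ED059, and disease resistance and P450 lists just above theirs. The medians of the latter were lower with members at 0 counts set to their bound, but random lists were not set alike. Jasmonate synthesis had 6 members higher and 7 lower (median 0.18, random -0.27 to 0.44), although its summed level was 13500 CPM in control and 8580 CPM in attacked leaves. This sum is carried by lipoxygenase L-5, Glyma15g03050.1, named after its values were seen, with 32222 and 13056 counts. The chloroplast 13S-lipoxygenase Glyma11g13880.2, named by rule, stood at 155 CPM in control and 39.1 CPM in attacked leaves. JAZ genes had 0 members higher and 1 lower of 5 (median 0.16; -0.07 with scaling by gene count totals), with TIFY 10A, Glyma13g17180.1, at 167 and 67.8 CPM. Protease inhibitors had 4 higher and 3 lower (median 0.35, random -0.32 to 0.64), and a cysteine proteinase inhibitor, Glyma13g04250.1, stood at 307 and 48.2 CPM. Phenylpropanoid entry enzymes had 0 higher and 3 lower (median -0.15), among them Glyma20g32135.1 at 56.1 and 18.6 CPM. The WRKY 40 gene Glyma07g02630.1 was 5.28-fold lower, as it was lower in Tianlong 2. Disease resistance proteins had 29 members higher and 14 lower of 110 (median 0.18, random -0.23 to 0.16; 0.15 with members at 0 counts set to their bound), with the TMV resistance protein N-like gene Glyma06g40710.1 at 13.9 and 116 CPM; under scaling by gene count totals this median was 0.00. The P450 list (26 higher, 13 lower, median 0.18, random -0.27 to 0.14; 0.07 at the bound) was at 0.00 there too. Ribosomal proteins had 31 members lower and 4 higher (median -0.11, random 0.04 to 0.33). Scaling by gene count totals put the median log2 fold of all genes at -0.13 (0.04 with TMM) and gave 1402 higher and 3827 lower genes (26.8% higher, against 40.1%), and the authors' library totals gave 1438 and 3774.

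Between control leaves, ED059 had higher transcripts of cell division genes than Tianlong 2 and lower transcripts of triterpene, heat shock and lipoxygenase genes. Of 17622 genes, 3005 were higher and 2645 lower in ED059. Cell division genes were higher for 67 of 129 members and lower for 6 (median 1.03, random -0.16 to 0.23). Histones were higher for 21 of 25 members (median 3.32) and kinesins for 25 of 39 (median 1.45), while cyclins were higher for 21 and lower for 3 of 65 (median 0.42). The kinesin Glyma02g37800.1 was at 0 counts in Tianlong 2 and at least 20.5-fold higher in ED059. The other member named for its fold, the kinesin Glyma14g15220.1, went the other way, with 54 counts in Tianlong 2 and 0 in ED059, at least 23.1-fold lower. Cell wall genes were higher for 38 and lower for 12 of 115 (median 0.30, random -0.17 to 0.23), with expansins higher for 8 of 17. Ribosomal proteins were higher for 20 and lower for 12 of 162 (median 0.37, random -0.27 to 0.01). The list found by terpenoid words holds 6 genes of the beta-amyrin branch of triterpenes, precursors of soyasaponins, and 5 of them were lower in ED059 (median -4.92, random -0.89 to 0.86; -4.50 with members at 0 counts set to their bound). Beta-amyrin synthase Glyma03g27661.1 stood at 83.5 CPM in Tianlong 2 and was at least 75.9-fold lower in ED059, and beta-amyrin 24-hydroxylase, Glyma08g46520.1, had 446 and 3 counts (log2 ratio interval -9.86 to -6.02).

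Heat shock genes were lower in control ED059 than in control Tianlong 2 leaves for 30 of 61 members and higher for 4 (median -0.99, random -0.24 to 0.31), and the high level in the Tianlong 2 control library given above enters this value. Jasmonate synthesis was lower for 11 and higher for 2 (median -0.69, random -0.42 to 0.32). Its 17 lipoxygenases were lower for 8 and higher for 1 (median -0.74). Its 15 other enzymes were lower for 3 and higher for 1 (median -0.27). The 9S-lipoxygenase Glyma07g03920.2, of the kind outside jasmonate synthesis, stood at 660 CPM in Tianlong 2 and 45.1 CPM in ED059. The summed level of the list was 13300 CPM in control Tianlong 2 and 13500 CPM in control ED059 leaves. The ED059 sum is carried by lipoxygenase L-5, as given with feeding in ED059, so these sums do not stand for the list as a whole. Photosystem and antenna genes were lower for 9 and higher for 2 of 37 (median -0.64, random -0.49 to 0.13), and disease resistance proteins lower for 35 and higher for 26 of 110 (median -0.40, random -0.12 to 0.32). Flavonoid enzymes (median -0.25, random -0.23 to 0.32) and P450s (-0.27, random -0.12 to 0.37) lay just below their random lists. WRKY factors did too (-0.25, random -0.19 to 0.40). With members at 0 counts set to their bound, P450s were at -0.19 and WRKY factors at -0.16, but random lists were not set alike. Protease inhibitors had 4 higher and 5 lower (median -0.44, random -0.66 to 0.32), with a trypsin inhibitor, Glyma08g45610.1, at 31.1 CPM in Tianlong 2 and 879 CPM in ED059.

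The genes of the next sentences were at 0 counts in control leaves of one genotype. The RD22-like gene Glyma04g35130.1, of a drought-responsive family, had 0 counts in Tianlong 2 and stood at 2820 CPM in ED059, at least 1990-fold higher. A sialidase-like gene, Glyma02g45690.2, was at least 218-fold higher in ED059, a small membrane protein, Glyma02g36640.1, at least 121-fold, a fatty acyl-CoA reductase, Glyma11g19160.2, at least 80.1-fold, a dehydrodolichyl diphosphate synthase, Glyma14g37210.1, at least 70.3-fold and the wax ester synthase-like gene Glyma06g44640.1 at least 44.6-fold. In the other direction a hydroxycinnamoyltransferase, Glyma18g12210.1, was at least 219-fold lower in ED059, a candidate of the rust resistance locus Rpp4, Glyma18g46120.3, at least 212-fold, a metalloendoproteinase, Glyma02g37990.1, at least 143-fold, a glutathione S-transferase, Glyma07g16810.1, at least 141-fold and a farnesyl pyrophosphate synthase, Glyma09g01820.1, at least 89.1-fold. Scaling by gene count totals put the median log2 fold of all genes at 0.28 (0.00 with TMM) and gave 4081 higher and 1948 lower genes (67.7% higher, against 53.2%), and the authors' library totals gave 3972 and 1990.

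Between attacked leaves the genotypes differed at more genes, 3664 higher and 3992 lower in ED059, and cell wall, jasmonate-repressor and protease inhibitor genes were higher in ED059 while phenylpropanoid, flavonoid, triterpene and P450 genes were lower. Cell wall genes, already higher in control ED059 leaves, were higher for 68 and lower for 22 of 115 members (median 1.38, random -0.30 to 0.23; 1.12 with members at 0 counts set to their bound). Expansins, proteins that loosen walls, were higher for 14 of 17, xyloglucan enzymes for 16 of 21 and pectin enzymes for 21 of 24, whereas cellulose synthase-like genes were higher for 9 and lower for 14 of 31. Pectinesterase Glyma17g04940.1 stood at 5.44 CPM in Tianlong 2 and 211 CPM in ED059. JAZ genes were higher for 3 of 5 (median 2.83, random -1.18 to 1.25), with TIFY 10B, Glyma04g01531.1, at 2.51 and 31.4 CPM and TIFY 10A, Glyma13g17180.1, at 8.78 and 67.8 CPM. In control leaves the JAZ median was -0.11 (0.19 with scaling by gene count totals). Protease inhibitors were higher for 7 and lower for 2 of 14 (median 1.06, random -0.55 to 0.80). The Bowman-Birk inhibitor Glyma18g46580.1 was at 0 counts in attacked Tianlong 2 and at least 434-fold higher in ED059, and the trypsin inhibitor Glyma08g45610.1 stood at 15.9 and 845 CPM.

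Phenylpropanoid entry enzymes were lower in attacked ED059 for 9 of 12 members (median -1.45, random -0.62 to 0.74), with the 4-coumarate ligase Glyma17g07190.2 at 272 CPM in Tianlong 2 and 11.8 CPM in ED059. Flavonoid enzymes were lower for 24 and higher for 12 of 62 (median -0.72, random -0.41 to 0.31), with a dihydroflavonol reductase, Glyma13g44700.1, at 518 and 9.09 CPM. The triterpene list was lower for 5 of 6 and higher for 1 (median -4.16), P450s for 50 of 94 with 20 higher (median -1.12, random -0.43 to 0.23), WRKY factors for 27 of 60 with 5 higher (median -0.81, random -0.48 to 0.33) and receptor kinases for 133 of 394 with 160 within 2-fold and the rest higher (median -0.39, random -0.25 to 0.05). Ribosomal proteins were higher for 60 of 162 (median 0.74) and cell division genes for 59 of 129 (median 0.73). Disease resistance proteins were lower for 40 and higher for 23 of 110 (median -0.40, random -0.37 to 0.22). The heat shock median was 0.00 and the photosystem median -0.01, while scaling by gene count totals put the median of all genes at -0.12. The metalloendoproteinase Glyma02g37990.1 stood at 2400 CPM in Tianlong 2 and 3.64 CPM in ED059, PR-1 protein Glyma15g06816.1 had 745 and 2 counts (log2 ratio interval -11.47 to -6.56), a prenyl transferase, Glyma15g39070.1, 666 and 3 counts (-9.96 to -6.12), and a lipid-transfer protein, Glyma18g05890.1, was at least 124-fold lower. The RD22-like gene Glyma04g35130.1 stood at 3.35 and 4400 CPM, and the GDSL lipases Glyma13g19220.1 and Glyma19g07080.1 were higher, the former at least 109-fold and the latter with 3 and 701 counts (6.44 to 10.27).

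A genotype difference held across both treatments for some of these genes. In the additive edgeR quasi-likelihood fit 523 genes passed an adjusted p of 0.05, 259 higher and 264 lower in ED059, and 2788 had an unadjusted p under 0.05. The cell division list had 15 of 129 members past the threshold, all higher in ED059, the triterpene list 5 of 6, all lower, and the heat shock list 5 of 61, all lower. Of the 523 genes, 508 differed by 2-fold or more the same way in control and in attacked leaves. The fit favours such genes, because its residual is the change of the genotype difference between treatments, so this share is no separate evidence. Of the 5 heat shock genes 2 did so, and the other 3 differed by 2-fold in control leaves alone, where the Tianlong 2 control library stood apart. P450s had 1 higher and 7 lower, disease resistance proteins 6 higher and 8 lower, cell wall genes 4 higher and 0 lower. The membrane protein gene Glyma02g36640.1 was at 0 counts in both Tianlong 2 libraries and at 171 and 305 CPM in ED059, at least 178-fold higher (edgeR adjusted p = 0.0111, higher in both treatments). The RD22-like gene Glyma04g35130.1 passed at adjusted p = 0.0121 in the edgeR fit (log2 fold 11.34, SE 1.46). Also higher past the threshold were the acyl-CoA reductase Glyma11g19160.2, an ankyrin repeat protein, Glyma14g04300.2, and the disease resistance protein Glyma03g05671.1. Lower were beta-amyrin synthase Glyma03g27661.1 (at least 55.9-fold), the lipid-transfer protein Glyma18g05890.1 (at least 75.0-fold), the GPI transamidase component Glyma18g35940.1, the farnesyl pyrophosphate synthase Glyma09g01820.1 and a mannose-1-phosphate guanylyltransferase, Glyma02g41820.1, all at 0 counts in both ED059 libraries. The count of calls depended on the fit: 213 with scaling by gene count totals and 1602 without a count minimum.

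No gene passed the same test for a feeding response common to both genotypes. The edgeR fit gave 0 genes at an adjusted p of 0.05, with 1233 genes at an unadjusted p under 0.05, and a smallest adjusted p of 0.241. DESeq2 gave 68 genes, 16 higher and 52 lower, with no adjusted p for 12299 genes, and edgeR gave 71 genes with a minimum of 50 counts and 220 without a minimum. Across genes the log2 responses of the genotypes correlated at r = 0.151, and no libraries are shared between them. Of 1815 genes at 2-fold or more in both, 574 were higher in both and 672 lower in both, where independent lists would share 295.4 and 451.5. In the opposite sense, 329 genes were higher in Tianlong 2 and lower in ED059, against 441.5 for independent lists, and 240 were lower in Tianlong 2 and higher in ED059, against 302.1.

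**Figure D2:**
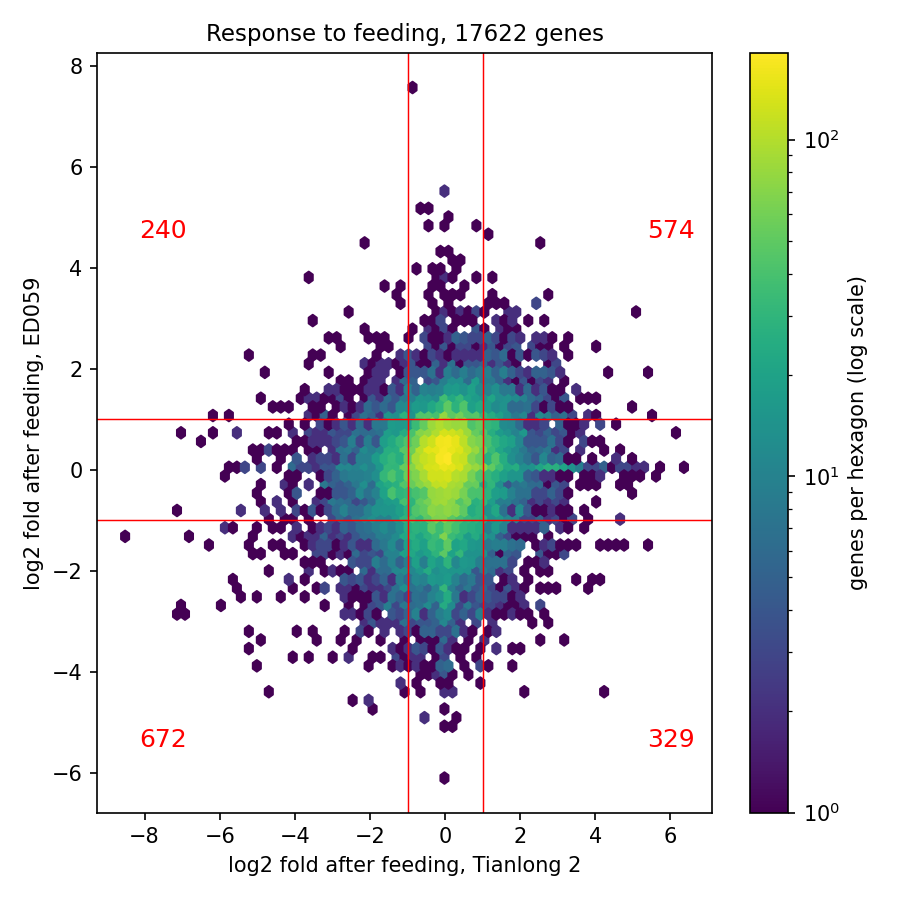
Log2 fold after feeding in ED059 (y axis) against that in Tianlong 2 (x axis) for 17622 genes, coloured by genes per hexagon on a log scale, each fold from 1 library against 1 other. Red lines mark 2-fold, and red numbers count genes beyond 2-fold in both genotypes, 574 and 672 in the same sense and 329 and 240 in opposite senses.

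The response to feeding itself differed by 2-fold or more between the genotypes for 7531 genes, 3447 with a higher log2 response in ED059 and 4084 with a lower one; no test of this difference is possible with 1 library per group. The 5 genes named for a higher response in ED059 all had 0 counts in attacked Tianlong 2 leaves, so their fitted differences and their order rest on the prior count. The Bowman-Birk inhibitor Glyma18g46580.1 had CPM of 8.96 and 0.0 in control and attacked Tianlong 2 and of 37.4 and 545 in ED059, a log2 difference of at least 6.70 with a floor of 3 counts. Small heat shock proteins Glyma07g32090.1, Glyma07g04860.1 and Glyma07g32030.1 were among them, with at most 17 counts in ED059. A nitrate reductase, Glyma14g33490.1, the enzyme that reduces nitrate for amino acid synthesis, stood at 56.6 CPM in control Tianlong 2, 0.0 CPM in attacked Tianlong 2, and 34.5 and 58.7 CPM in ED059. In the other direction vacuolar processing enzyme 2, Glyma14g10620.1, stood at 31.6 and 679 CPM in Tianlong 2 and 79.6 and 26.8 CPM in ED059. The fasciclin-like, auxin-induced and boron transporter genes named above were also in this group, with at most 4 counts in either ED059 library, so their fitted differences rest on the prior count as well. The receptor-like kinase Glyma13g27130.1 had 22 and 30 counts in Tianlong 2 and 304 and 6 in ED059. Scaling by gene count totals gave 2158 genes with a higher and 5503 with a lower response in ED059.

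**Figure D3:**
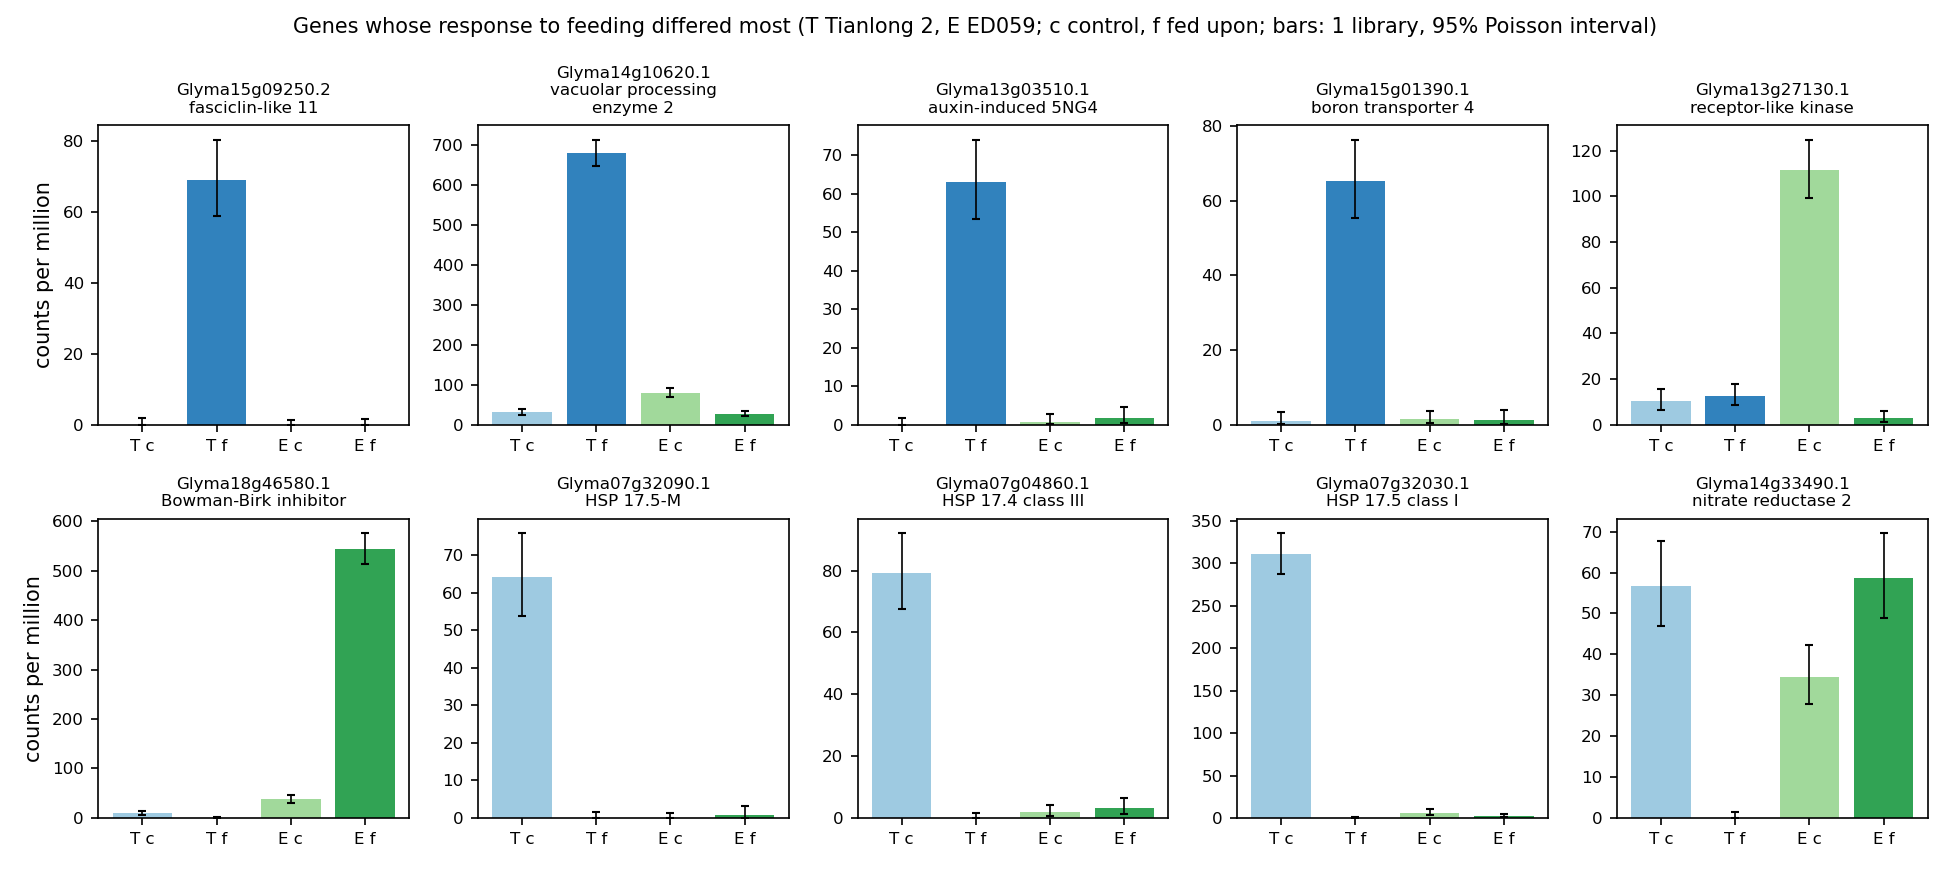
CPM (y axis, linear from 0) in each library of the 10 described genes with the largest fitted differences of the response to feeding between the genotypes; T is Tianlong 2, E is ED059, c control and f fed upon, each bar is 1 library and error bars are exact Poisson 95% intervals of counting error. The Bowman-Birk inhibitor reached 545 CPM in attacked ED059 leaves, and vacuolar processing enzyme 2 reached 679 CPM in attacked Tianlong 2 leaves.

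The remaining lists stood mostly within their random lists after feeding, and some stood apart between the genotypes. After feeding, medians in Tianlong 2 and ED059 were -0.10 and 0.15 for phenol oxidases and peroxidases, -0.03 and -0.13 for ethylene factors, 0.00 and -0.04 for MYB factors, -0.12 and 0.05 for calcium-binding proteins, 0.07 and 0.30 for Calvin cycle enzymes, 0.15 and 0.27 for glutathione S-transferases, and 0.02 and 0.11 for starch and sucrose enzymes. None of these 14 medians lay outside the central 95% of random lists, and several near 0 change sign under scaling by gene count totals. Between genotypes, glutathione S-transferases were below random lists in ED059 in control (median -0.50, random -0.44 to 0.40) and attacked leaves (-0.59, random -0.56 to 0.54). Ethylene factors were above them in control leaves (0.35, random -0.20 to 0.28), and phenol oxidases and peroxidases in attacked leaves (0.53, random -0.52 to 0.37). Receptor kinases had medians after feeding of 0.13 and 0.02 (-0.11 in ED059 with scaling by gene count totals), inside their ranges. Clock genes stood above their random lists in Tianlong 2 (median 0.48, random -0.48 to 0.41). Markers of other organs were scarce: the 2 seed storage genes summed to between 7.55 and 20.1 CPM and the 3 pollen genes to between 35.1 and 52.8 CPM. The 3 senescence genes summed to 274 and 304 CPM in Tianlong 2 and to 111 and 156 CPM in ED059. The 9 nodule genes summed to between 151 and 284 CPM, with a median of 0.73 after feeding in ED059 (random -0.85 to 0.63).

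The authors' deposited tables give their own calls, from 1 library against 1 other. At an FDR of 0.001 or less and a log2 ratio of 1 or more, the authors' deposited table for Tianlong 2 holds 1522 higher and 1129 lower genes after feeding, and the one for ED059 holds 565 higher and 2048 lower. The authors' deposited tables for the genotypes hold 2147 higher and 1136 lower genes in control ED059 leaves, and 1985 higher and 2741 lower in attacked ED059 leaves. In the authors' deposited table of pathways for feeding in Tianlong 2, flavonoid biosynthesis had 47 called genes, 31 higher and 16 lower, and alpha-linolenic acid metabolism 18, of which 15 were lower. In the authors' deposited table for feeding in ED059, the ribosome had 68 called genes, 64 of them lower. In the authors' deposited table of processes for control leaves, nucleosome organization had 35 called genes, 35 of them higher in ED059.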

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

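The tests below of a state of the Tianlong 2 control library, of feeding in both genotypes, of exchanged labels and of a response that differs were chosen only after the results were seen; the others were written before. The lists and genes of the next paragraph stood out because their log2 fold after feeding, for lists the median, had opposite signs in Tianlong 2 and ED059. For the lists this is a difference of sign only, since their ED059 medians all lay within random lists. None of these differences was tested, because each group is 1 library.

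Of the gene lists, jasmonate synthesis had medians of -0.65 in Tianlong 2 and 0.18 in ED059, a median difference of 1.06 (ED059 minus Tianlong 2). JAZ repressors had -2.62 and 0.16 with a median difference of 2.63, and protease inhibitors -1.19 and 0.35 with 1.58. Phenylpropanoid entry enzymes had 1.47 and -0.15 with a median difference of -1.40. Photosystem and antenna genes had -0.32 and 0.28 with 0.91, but both medians lay within random lists, whose own medians were -0.17 and 0.22 with a difference of 0.38 (-0.01 to 0.78). Cell wall genes had -0.61 and 0.03 with 0.56. With scaling by gene count totals the ED059 medians of JAZ and cell wall genes were -0.07 and -0.16, so their opposite sense was lost. Of single genes, vacuolar processing enzyme 2, Glyma14g10620.1, had log2 folds of 4.39 and -1.54, a difference of -5.93, and the Bowman-Birk inhibitor Glyma18g46580.1 had fitted values of -3.53 and 3.83, a difference of 7.37. The former and the difference depend on the prior count, since attacked Tianlong 2 had 0 counts; with a floor of 3 counts the gene was at least 7.14-fold lower there and the difference at least 6.70.

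The lower JAZ and protease inhibitor genes in attacked Tianlong 2 leaves invite a second look, because jasmonate and wounding are known to raise both. A raised state of the Tianlong 2 control library alone would give no genotype difference in attacked leaves, which leave that library out. There, in ED059 against Tianlong 2, the JAZ and protease inhibitor lists were at percentiles 99.9 and 99.5. This argues against that state as the sole cause for these lists. In control leaves both lay within random lists, but with only 5 JAZ genes this cannot exclude a raised level. The jasmonate synthesis list went the other way, at percentile 0.1 in control and 95.6 in attacked leaves. For that list a raised state stays open. Exchanged treatment labels of the Tianlong 2 libraries would turn the sign of its response, including that of phenylpropanoid entry enzymes, higher for 11 of 12 members as labelled. The responses correlated at 0.151, above 0, which speaks against an exchange only if the genotypes share a response, and levels across genotypes went both ways (0.789 and 0.718 as labelled, 0.815 and 0.635 if exchanged), so it cannot be told apart from the labels as given without a second library. A response to feeding that differs between the genotypes, with the smaller median difference at 1.58, stays open for the same reason.

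Heat shock genes were lower after feeding in Tianlong 2, and the control library of Tianlong 2 stood apart: its summed level was 3.02 times the highest of the other 3 libraries, and the genotype difference in attacked leaves lay at percentile 53.8 of random lists. This describes the pattern that prompted the test and does not test its cause, so a state of that control library stays open. Reads shared between near-identical small heat shock genes are argued against as the whole cause, since the 23 members of the larger families had a median of -1.10 (bootstrap over members -2.61 to -0.65), where a median above -0.5 was the mark of that cause. The limits were written before, but the sorting of members into families was corrected, and the interval added, after a first value was seen. Sharing of reads among copies within the larger families was not tested, so shared reads in general stay open. Lowering by feeding in both genotypes remains open, with the ED059 median at percentile 9.2. In ED059, 22 of 61 members were lower and 4 higher. There the 8 heat shock factors had a median of -1.31 and the 11 other members -1.20, but the larger families -0.16. The 19 small heat shock proteins, the lowest family in Tianlong 2 at -4.82, had a median of 0.03 in ED059. Some of them had few counts in ED059, such as Glyma07g04860.1 with 5 and 7. The 2 list members named for the largest folds in ED059 were small heat shock proteins, and both were lower after feeding. Glyma07g32050.1 stood at 121 and 11.8 CPM and Glyma19g01440.1 at 33.4 and 4.09 CPM.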

How the results depend on the processing

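Alternatives with the authors' library totals, with the authors' per-million values, and all those for the difference of responses and for the number of lists were chosen after seeing the data. No paired analysis was possible because each group holds 1 library, and leaving a library out would remove a group. The planned ratio of RPKM values was not run, since the tables hold per-million values; their log2 ratio with a pseudocount of 1 stood in for it.

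Counts of genes at 2-fold followed the count minimum by construction. In the order feeding in Tianlong 2, feeding in ED059, genotypes in control leaves, genotypes in attacked leaves, a minimum of 50 counts gave 2424, 2303, 2548 and 3732 genes, the 4-fold limit 1572, 1299, 2079 and 3133. No minimum gave 7845, 7747 and 8797 in the first 3 and stayed within 1.5 times in attacked leaves. The per-million values gave 4014, 3913 and 4664, totals within 1.5 times, but their higher or lower genes alone moved further. Other scalings and the prior count kept the totals within 1.5 times. Count totals and the authors' totals moved the splits given in the report, and DESeq2 size factors did so less. A prior count of 0.5 left the splits close, with 50.2%, 40.8%, 53.7% and 47.7% higher against 49.4%, 40.1%, 53.2% and 47.9%. For the common feeding response, 0 genes became 220 without a minimum, 71 with a minimum of 50 and 68 with DESeq2; the cause was not tested. The 523 genotype calls became 213 with count totals, 1602 without a minimum and 123 without the treatment term. The difference of responses gave 7661 genes with count totals (2158 and 5503) and 3437 with a minimum of 50. The correlation of responses was 0.222 with a minimum of 50 counts.

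Of the 112 list medians, 42 lay outside random lists, and 42, 43 and, of 108, 40 did with count totals, DESeq2 size factors and a minimum of 50, each against 2000 random lists instead of 10000. Of these 42, 40, 42 and 32 stayed outside, in the same order. No named gene changed direction under count totals or a prior count of 0.5, and 13 of 226 values moved beyond their counting interval. Depth limits single genes: near 10 counts, a 2-fold difference lies within counting error.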

Other observations

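The splits of lists by family were made after the list values were seen. The tests of absent genes in the last paragraph were written before their results were seen, apart from the change given there for sampling of few counts. Within the jasmonate list in ED059, the 17 lipoxygenases had a median of 0.27 after feeding, with 4 higher and 2 lower, and the 15 other enzymes -0.50, with 2 higher and 5 lower; this split was not tested. In Tianlong 2 the medians were -0.51 and -1.03. The 5 flavonoid genes found by the words chalcone and synthase were higher for 4 members after feeding in Tianlong 2 (median 1.07). They include Glyma20g03900.1, described as a 6'-deoxychalcone synthase, so the values are not of chalcone synthases alone. Against Tianlong 2 they had a median in ED059 of -1.45 in control leaves, with 3 of 5 lower, and of -2.72 in attacked leaves. The 6 phenylalanine ammonia-lyases were all higher after feeding in Tianlong 2 (median 1.54); in ED059, 0 were higher and 2 lower, with a median of 0.39.

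Wall enzymes also split by kind. After feeding in Tianlong 2, xyloglucan enzymes had a median of -1.82, with 15 of 21 lower, and pectin enzymes -1.37, with 15 of 24 lower, while the 31 cellulose synthase-like genes had a median of 0.02, with 11 higher and 7 lower. Ribosomal proteins of the chloroplast or of bacterial type, 53 members, had a median of -0.46 after feeding in Tianlong 2, close to the -0.60 of the other 109. In control leaves their genotype medians were 0.05 and 0.47. The level of the Tianlong 2 control library correlated at 0.815 with attacked ED059, and attacked Tianlong 2 at 0.635 with control ED059.

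Some genes had counts in both libraries of one genotype and 0 in both of the other: with a minimum of 20 counts, 58 were at 0 in ED059 and 48 at 0 in Tianlong 2, and with a minimum of 50 counts 16 and 12. For sampling of few counts, the limit written before concerned the expected number alone. Any data meet it with a minimum of 20 counts, so it decided nothing. The number found was brought in afterwards: 106 genes, where 2.3e-10 would be expected from equal levels, which argues against sampling of few counts as their cause. Reads of the wild line lost on a cultivar reference would place most of these genes at 0 in ED059; the share was 54.7% (exact 95% interval 44.8% to 64.4%), which leaves this open, and genes that are missing from or silent in one genotype stay open too. Reads assigned to another copy stay open as well: of the 34 such genes that share their description with another gene, 7 (20.6%) had such a gene 4-fold or more the other way in both treatments, at percentile 98.1 of random genes with ties halved (median 8.8%), which is equal to and not above their upper limit of 20.6%.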
